A study of Mus musculus with 190 samples.

How the data were processed

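Whole-blood RNA was measured in 190 libraries from male NC/Nga mice, an inbred strain that can develop dermatitis resembling atopic dermatitis under conventional housing. Per the labels' protocols, about 0.1 mL of blood was drawn from the tail vein into EDTA-coated capillaries without anesthesia. RNA was isolated with the NucleoSpin RNA Blood kit, and stranded total-RNA libraries were made with the TruSeq kit that depletes ribosomal and globin RNA. Each label gives the housing, the cohort, the sampling day, the replicate number and a visible dermatitis score. The 20 groups are the first and the second sampling of 9 conventional cohorts of 10 mice and of 1 specific-pathogen-free (SPF) control cohort of 5 mice.

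The authors deposited 1 table of expected counts per gene, in which 2.86% of all values were not whole numbers. Per the submitters' processing notes the reads were processed with DRAGEN on genome build GRCm39. The DRAGEN version, the annotation release and any read filter are not given in the sources used here. The table lists 55414 genes by versioned Ensembl identifier with symbol, type and position. Of its symbols 980 occur more than once, so those genes were kept apart by identifier. All 190 count columns were matched to samples by library name and 0 were left unused. The reference annotation at hand is of another build and was not used. Total counts per library ran from 21444113 to 71967285 with a median of 36448166. The RNA component genes Rn7s2 and Rn7s1 took 11.2% and 10.5% of all counts, the mitochondrial rRNA gene mt-Rnr2 took 10.7% and the globin gene Hbb-bs took 4.29%, which leaves less depth for all other genes than the totals show.

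Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr over the 20 groups (minimum count 10, minimum total 15), which left 18192 genes. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 values are the absolute log2 value divided by the square root of F. All edgeR tests were two-sided. Genes with near-identical copies, among them Stfa1, Stfa2l1, Ly6g, the Oas1 genes, the hair keratins and the globins, may share reads, and their values are uncertain to that extent.

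Conventional and SPF mice were compared on day 16 within a fit of the 30 libraries of cohort 5 and the SPF cohort, and on day 44 with all 50 conventional libraries of that day. The same 30 libraries gave the change from day 16 to day 44 in each housing and the difference of these changes. The 90 first-sampling conventional libraries were tested for any difference among 9 days and for a linear trend per 10 days. The second sampling was compared with the first over 180 conventional libraries with cohort as a covariate. Slopes on the dermatitis score were fitted with cohort as a covariate over the 90 second-sampling libraries and over the 60 first-sampling libraries of days 12 to 30, and the difference of these slopes was tested over 150 libraries. Spread between the libraries of a day was compared with that of the other days by a Brown-Forsythe test per gene on log2(CPM + 1) residuals from the day median. It used 100 permutations of residuals between days, whose smallest possible p is 0.0099. A comparison of first-sampling expression with the later score of the same mouse was planned only if replicate numbers were found to pair the libraries. The criterion for this, a correlation over 0.1 in every pair, was not met, so it and its alternatives were not run.

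Before the data were examined, 30 gene lists of cell types and pathways were fixed, along with the tests and the rule for named genes. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists, and again with an estimated correlation. Of the list calls made over 10 comparisons with the preset value, 1 passed with an estimated correlation, that of the eosinophil genes on day 16. Permutation tests of list means over libraries, adjusted over the 30 lists, were added after the data were seen. For the housing comparisons and the change from day 16 to day 44 in each housing, every arrangement of libraries was used, called exact here. The other comparisons used 100000 permutations. Like the edgeR tests, these permutation tests take single libraries as units. Where the same cohort was sampled on both days compared, its repeated samples were taken as independent. The p of such a change is therefore not exact for repeated mice. Housing and first sampling day are set per cohort, so for them no p measures the spread between cohorts. The enrichment of Biological Process terms given in the deposited table was also added, by a hypergeometric test against tested genes that have a term. For each comparison the rule for named genes took the 10 largest rises and 10 largest falls among called genes with a mean of at least 2 CPM. Immunoglobulin and T cell receptor segments, predicted genes, small RNA genes and globins were left out. The rule added the 3 largest each way for each day against day 2, up to 4 members with the smallest p of each called list, and Ighe, Ighg1 and Il4 for the score. That rule gives 707 gene values with an effect size. After these values and their alternatives had been seen, the list members were narrowed to the 2 with the smallest p in each of the 6 called lists with the smallest camera p per comparison. Of the list members so chosen, 1 value is not reported here. An earlier hand selection of list members was discarded because it was made with the alternatives in view.

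Scripts were tested on simulated counts drawn from the means and library sizes of these libraries with 200 changed genes. In the day 16 comparison 69% of genes changed by 1 log2 unit and 98% of those changed by 2 were recovered, and on day 44 these were 70% and 95%. For the trend 89% of slopes of 0.25 were recovered, for the second-sampling score 83%, and for the first-sampling score 43%. Of all calls in these simulations 6.7% were false for day 16, 9.34% for day 44, 20.8% for the trend, 13.3% for the second-sampling score and 7.38% for the first-sampling score. Of the trend, 34 of the 49 false calls were among the 2281 genes with a dispersion over 1. In the data, 866 of 9569 genes called for the trend had such a dispersion. In the spread test, 200 of 5000 simulated genes were given 4 times the SD on day 9, 216 genes were called on that day and at most 1 on another.

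No pair of libraries within a group was a duplicate: the lowest chi-square per gene between 2 libraries was 17.2. The alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, no filter on low counts, and leaving out globin, rRNA and mitochondrial genes or each SPF library. Others were the replicate number as a block, covariates for cell composition (mean log2 CPM of 4 cell type lists), restrictions by score, and cohorts 1 to 3 alone for the second against the first sampling. For the spread they were another pseudocount, another filter and leaving out the library farthest from its day median. Added after seeing the data were covariates for the share of counts on mitochondrial rRNA and globin genes, a covariate for the skin and muscle list, and fits within sets of cohorts or without libraries on 1 side of 5% globin or without cohort 5 day 44 replicate 5. The sets and shares were added because library shares differed between cohorts, which no label explains.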

Results

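Gene counts from whole blood were compared between 9 cohorts of male NC/Nga mice in conventional housing, which develop dermatitis resembling atopic dermatitis, and 1 SPF cohort that stayed at a dermatitis score of 0. Each conventional cohort of 10 mice was first sampled on its own day (2, 5, 9, 12, 16, 19, 23, 26 or 30). It was sampled again on day 44 (cohorts 1, 3, 5, 7 and 9) or day 40 (cohorts 2, 4, 6 and 8), and the 5 SPF mice were sampled on days 16 and 44. In the first sampling 58 of 90 conventional libraries had a score of 0, with none above 0 before day 12 and a mean of 1.65 ± 0.75 (SD, n = 10) on day 30. In the second sampling 7 of 90 had a score of 0 and 67 a score of 2 or more. Total counts ranged from 21444113 to 71967285 per library with a median of 36448166.

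Libraries differed by cohort in the share of counts on globin and mitochondrial rRNA genes. The median globin share was 3.58% in the 80 libraries of cohorts 1 to 4, 6.84% in the 20 of cohort 5, 7.83% in the 80 of cohorts 6 to 9 and 3.59% in the 10 SPF libraries. The median mitochondrial rRNA share was 6.92%, 14.7%, 15.4% and 7.38% in the same order. Because each first sampling day belongs to 1 cohort, day and cohort cannot be told apart in the first sampling. For the trend, the second against the first sampling and the second-sampling score, the lists named first also have values within cohorts 1 to 4 and within cohorts 6 to 9.

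**Figure D1:**
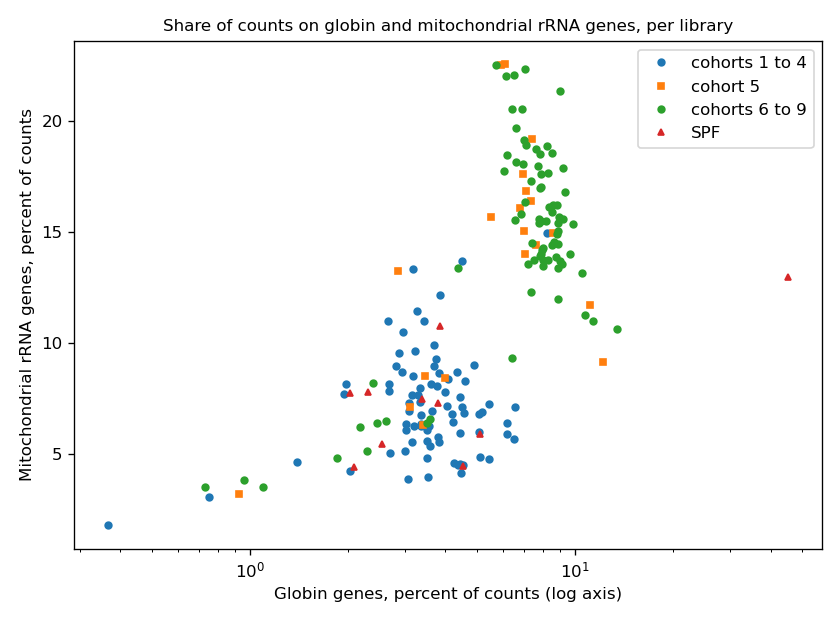
Share of counts on globin genes (percent, log axis) against the share on mitochondrial rRNA genes (percent) for each of the 190 libraries, by set of cohorts. Cohorts 6 to 9 have medians of 7.83% globin and 15.4% mitochondrial rRNA, and cohorts 1 to 4 have 3.58% and 6.92%.

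On day 16, when 8 of 10 mice of cohort 5 still had a score of 0, blood of conventional mice held more transcripts of eosinophil genes than blood of SPF mice. Ccr3, the eotaxin receptor (ENSMUSG00000035448.10, GRCm39 chromosome 9, 123822009 to 123831726, plus strand), was higher by 2.39 ± 0.40 (log2 ± SE, edgeR adjusted p = 0.0036), with 16.6 ± 2.6 CPM (SD, n = 10) against 3.12 ± 2.80 CPM (n = 5). Siglecf, a sialic acid-binding receptor of eosinophils, was higher by 2.26 ± 0.38, and Alox15, which oxidises arachidonic acid, by 2.22 ± 0.41. Steap4, a metalloreductase of the mature neutrophil list (ENSMUSG00000012428.10, chromosome 5, 8010457 to 8032213, plus strand), was higher by 3.39 ± 0.75 (adjusted p = 0.032). The interferon-induced genes Oasl2 and Rtp4 were higher by 1.76 ± 0.40 and 1.33 ± 0.31. H2-Ab1, a chain of MHC class II, was lower by −0.86 ± 0.18, as were Cxcr5, the B cell follicle homing receptor (−0.83 ± 0.19), and Cd69, an early activation marker (−0.88 ± 0.19).

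By list, 4 of 12 eosinophil genes were higher on day 16 and 7 were called when adjusted over the list alone (adjusted p = 0.00213 with an estimated correlation). Their mean difference was 1.11 ± 0.16 (exact permutation p = 0.000333, adjusted 0.00999). Each housing is 1 cohort on this day, so this p measures spread between libraries only. Of the 20 mature neutrophil genes 1 was higher and 7 were called when adjusted over the list alone (adjusted p = 0.354 with an estimated correlation). Of the 30 type I interferon-stimulated genes 2 were higher and 6 were called adjusted over the list alone (adjusted p = 0.271 with an estimated correlation). Of the 10 MHC class II genes 1 was lower and 9 were called adjusted over the list alone (adjusted p = 0.256 with an estimated correlation). None of the 17 B cell genes or 28 cytosolic ribosomal protein genes was called over all genes, while 10 and 15 were called adjusted over the list alone. Their medians were −0.58 and −0.31 (both with an adjusted p = 0.259 with an estimated correlation). In all 97 genes were called, 69 higher and 28 lower, and 460 by DESeq2.

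The day 16 count was 1.5e+02 (2 digits) without SPF replicate 1, 49 without replicate 2, 31 without replicate 4 and 39 without replicate 5, and with the cohort 5 libraries under 5% globin alone it was 1, that of Gapt, chosen after its values were seen. It was 463 with the rRNA and globin shares as covariates, 46 with the replicate number as a block and 55 without a filter on low counts. The largest fall, that of the mitochondrial leucyl-tRNA synthetase gene Lars2 (−5.37 ± 0.85), rested on SPF replicate 3, which had 675 CPM and 45.3% of its counts on globin genes and without which the difference was −0.02.

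**Figure D2:**
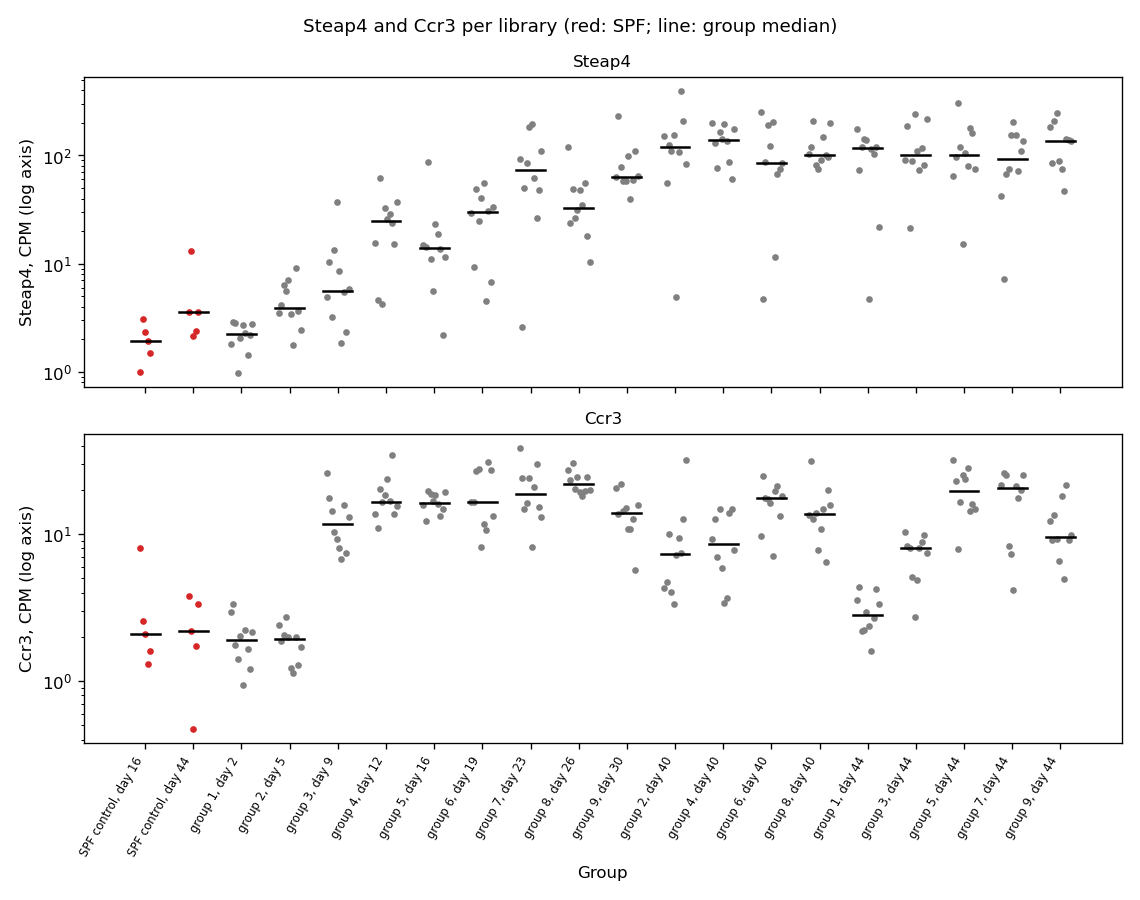
Steap4 and Ccr3 in CPM (log axis) in each library of the 20 groups, SPF in red, with a line at each group's median. Median Steap4 was 1.91 CPM in SPF mice and 13.9 CPM in cohort 5 on day 16, and median Ccr3 was 1.91 CPM on day 2 and 11.7 CPM on day 9.

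On day 44, neutrophil genes were far higher and B cell genes lower in conventional than in SPF mice. Steap4 was higher by 4.50 ± 0.66 (edgeR adjusted p = 6.7e-06), Ly6g, a surface marker of neutrophils, by 4.65 ± 0.93, Acod1, which makes itaconate, by 4.15 ± 0.65, and Chil3, a chitinase-like secreted protein, by 3.94 ± 0.71. Asns, asparagine synthetase, was higher by 4.29 ± 1.20 and Oas1e, of the oligoadenylate synthetase family, by 5.19 ± 1.45. Cd79b, a signalling chain of the B cell receptor, was lower by −1.36 ± 0.22 and Fcer2a, the low-affinity IgE receptor, by −1.36 ± 0.28. Acan, the cartilage proteoglycan aggrecan, was lower by −5.39 ± 1.05, which turned to 6.62 without SPF replicate 3. Spp1, osteopontin, was lower by −3.09 ± 0.69, with 130 CPM in SPF replicate 3 and at most 8.54 CPM in the other SPF libraries, and at −0.53 it was not called without that replicate.

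All 20 mature neutrophil genes were higher on day 44, among them Clec4e (2.96 ± 0.44), and all 20 were called adjusted over the list alone (adjusted p = 0.0697 with an estimated correlation). Their mean difference was 2.63 ± 0.40 (exact permutation p = 1.73e-06). This p takes single libraries as units, with 1 SPF cohort, and does not measure spread between cohorts. Of the 13 complement and acute phase receptor genes 10 were higher, as Fpr1 (2.57 ± 0.42) and Fcgr3 (1.80 ± 0.31) were, and 10 were called adjusted over the list alone (adjusted p = 0.0697 with an estimated correlation). Of the 22 erythroid genes 16 were higher, among them the mitochondrial iron importer Slc25a37 (1.71 ± 0.50), and all 22 were called adjusted over the list alone (adjusted p = 0.333 with an estimated correlation). The globin list mean was also higher, by 1.55 ± 0.38 (exact permutation p = 0.000219, adjusted 0.00082). On that day the median globin share was 3.4% in SPF mice, 3.65% and 3.71% in cohorts 1 and 3, and 7.03%, 7.52% and 7.46% in cohorts 5, 7 and 9. In SPF mice the erythroid list mean was 7.71 ± 0.32 log2 CPM (SD, n = 5) on day 44 and 8.43 ± 0.23 on day 16. This lower value in SPF mice did not pass the adjustment over lists (exact permutation p = 0.00794, adjusted 0.119). Of the 30 type I interferon-stimulated genes 14 were higher and 18 were called adjusted over the list alone (adjusted p = 0.173 with an estimated correlation). Of the 17 B cell genes 16 were lower and 17 were called adjusted over the list alone (adjusted p = 0.191 with an estimated correlation). All 10 MHC class II genes were lower, all 10 also adjusted over the list alone (adjusted p = 0.173 with an estimated correlation).

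In all 3648 genes were called on day 44, 1785 higher and 1863 lower, against 2581 higher and 1738 lower with DESeq2. The count was 2411, 1996 and 2276 without SPF replicates 2, 3 and 4 and 303 with cell composition as covariates, under which Ly6g turned to −0.49. With the 8 conventional libraries of score 0 or 0.5 alone, of 50, edgeR called 0 genes, with 2861 at an unadjusted p under 0.05. So small a set cannot show that mice of low score are like SPF mice.

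From day 16 to day 44, mature neutrophil genes rose in cohort 5. Steap4 rose by 2.55 ± 0.53, Acod1 by 2.66 ± 0.49 and Ly6g by 2.68 ± 0.67. Col1a1 and Col1a2, the chains of type I collagen, fell by 3.44 ± 0.50 and 3.20 ± 0.50 and Sparc, a matrix glycoprotein, by 2.65 ± 0.42. The hair keratin genes Krt81, Krt83 and Krt86 were called higher by 5.12 ± 1.59, 4.66 ± 1.47 and 4.89 ± 1.37 through 1 library. Day 44 replicate 5 had 88.4, 60.5 and 66.5 CPM and no other library of that day over 0.292, and without it the values were −3.33, −2.30 and −0.92, not called. All 20 mature neutrophil genes rose, as Cxcr2, a chemokine receptor of neutrophils, did (1.81 ± 0.30), all 20 also adjusted over the list alone (adjusted p = 0.204 with an estimated correlation). Of the 30 type I interferon-stimulated genes 12 rose and 18 were called adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). Of the 17 B cell genes 9 fell and 12 were called adjusted over the list alone (adjusted p = 0.349 with an estimated correlation).

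Between the same days, 2287 genes were called in cohort 5 (1461 higher, 826 lower), and 537 in its libraries with 5% globin or more, where Ly6g (3.15) was not called. The libraries of cohort 5 also differed between the days. The median globin share was 3.72% on day 16, with 6 of 10 libraries under 5%, and 7.03% on day 44, with 0 of 10. The median mitochondrial rRNA share was 10.1% and 15.9%, and the globin list mean rose by 1.08 ± 0.41 (exact permutation p = 0.0107, adjusted 0.0248). In SPF mice edgeR and DESeq2 both called 0 genes, with 1052 at an unadjusted p under 0.05 by edgeR. Of the 16 monocyte genes none was called over all genes in SPF mice and 2 were adjusted over the list alone, with a median of 0.58 (adjusted p = 0.0597 with an estimated correlation). Their list mean changed by 0.55 ± 0.13 and that of the erythroid genes by −0.73 ± 0.18 (both exact permutation p = 0.00794, adjusted 0.119). None of the 22 erythroid genes was called in SPF mice, nor adjusted over the list alone (adjusted p = 0.626 with an estimated correlation). In cohort 5 the erythroid list mean changed by 0.16 ± 0.32 (exact permutation p = 0.6249), and the difference of the changes was 0.88 ± 0.47 (permutation p = 0.0615, adjusted 0.168). For the difference of the 2 changes edgeR called 0 genes, with 1892 at an unadjusted p under 0.05, and DESeq2 called 55. With the replicate number as a block edgeR called 36, and 1 gene in SPF mice (Col10a1, chosen after its values were seen); whether the number stands for the same mouse stays open. The mature neutrophil list mean rose by 1.66 ± 0.60 more in cohort 5 (permutation p = 0.00816, adjusted 0.118), and 14 of its 20 genes were called adjusted over the list alone.

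Over the first sampling days as a whole, mature neutrophil and type I interferon-stimulated genes rose and B cell and cytosolic ribosomal protein genes fell, not all of them within each set of cohorts. Acod1 rose by 1.85 ± 0.19 per 10 days (log2 ± SE), Steap4 by 1.75 ± 0.16 and Wfdc17 by 1.59 ± 0.14. S100a8 and S100a9, which form calprotectin, rose by 1.43 ± 0.14 and 1.36 ± 0.13. Steap4 stood at 2.19 ± 0.64 CPM (SD, n = 10) on day 2 and 86.2 ± 55.7 CPM on day 30. Oasl2 rose by 1.07 ± 0.08 and Ifih1, a sensor of double-stranded RNA, by 0.42 ± 0.04. Col10a1, a collagen of hypertrophic cartilage, fell by 2.37 ± 0.18, Cd79b by 0.54 ± 0.05 and the ribosomal protein gene Rpl3 by 0.25 ± 0.02.

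All 20 mature neutrophil genes rose with day, all 20 also adjusted over the list alone (adjusted p = 0.169 with an estimated correlation). The list mean rose by 1.02 ± 0.09 per 10 days (permutation p = 1e-05, the smallest that 100000 permutations can give). It rose by 1.47 ± 0.25 within cohorts 1 to 4 and was 0.66 ± 0.37 within cohorts 6 to 9 (permutation p = 0.0817, adjusted 0.245). Over the 58 libraries of score 0 it rose by 0.83 ± 0.12. Of the 30 type I interferon-stimulated genes 25 rose, 25 also adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). Their mean rose by 0.28 ± 0.03, with 0.14 ± 0.09 within cohorts 1 to 4 (permutation p = 0.135) and 0.28 ± 0.13 within cohorts 6 to 9 (permutation p = 0.0366, adjusted 0.22). Of the 17 B cell genes 15 fell, 15 also adjusted over the list alone (adjusted p = 0.227 with an estimated correlation). Their mean slope was −0.33 ± 0.09 within cohorts 1 to 4 and −0.10 ± 0.23 within cohorts 6 to 9 (permutation p = 0.68). Of the 28 cytosolic ribosomal protein genes 23 fell and 25 were called adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). Their mean slope was −0.31 ± 0.06 within cohorts 1 to 4 (permutation p = 1e-05) and 0.0059 ± 0.0443 within cohorts 6 to 9 (permutation p = 0.896).

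Eosinophil genes followed another course. Ccr3 was higher on day 9 than on day 2 by 2.69 ± 0.24 (edgeR adjusted p = 8.3e-14), at 12.9 ± 5.9 against 1.97 ± 0.75 CPM (SD, n = 10 each), and on day 16 by 3.04 ± 0.24. The eosinophil list mean rose by 1.30 ± 0.14 per 10 days within cohorts 1 to 4 (days 2 to 12; permutation p = 1e-05) and was −0.12 ± 0.11 within cohorts 6 to 9 (days 19 to 30; permutation p = 0.274). From the first to the second sampling it fell by 0.15 ± 0.05 (permutation p = 0.00264, adjusted 0.00305), with −0.07 ± 0.08 within cohorts 1 to 4 (permutation p = 0.417) and −0.29 ± 0.07 within cohorts 6 to 9. Over all days 7 of 12 eosinophil genes rose, 7 also adjusted over the list alone (adjusted p = 0.17 with an estimated correlation).

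In all 10526 genes differed among the 9 days and 9569 had a trend (4425 up, 5144 down), with 4212 trends within cohorts 1 to 4 and 498 within cohorts 6 to 9. Against day 2, 50 genes were called on day 5, 435 on day 9, 2216 on day 12, 2224 on day 16, 5523 on day 19, 6803 on day 23, 5702 on day 26 and 6902 on day 30. Acan, Car3, Peg3 and Susd5 were called lower over all days, and within cohorts 1 to 4 their slopes were 0.60, 0.0341, 1.02 and 0.66. On day 16 Acan had a median of 0.22 CPM and reached 276 CPM in 1 library.

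**Figure D3:**
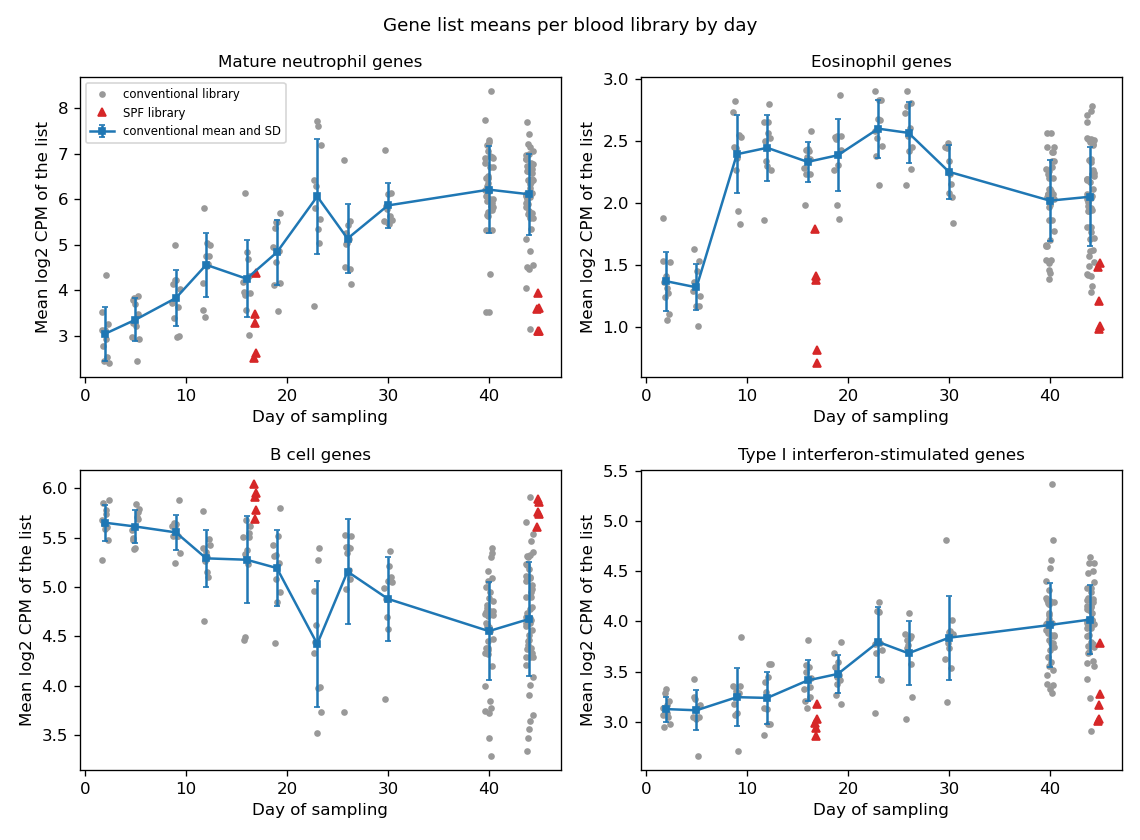
Mean log2 CPM of the mature neutrophil, eosinophil, B cell and type I interferon-stimulated lists against the sampling day, with a dot per conventional library, the mean and SD of each day, and SPF libraries as triangles drawn 1 day to the right. Over days 2 to 12 the eosinophil list climbs by 1.30 and the mature neutrophil list by 1.47 per 10 days. Over all first sampling days they climb by 0.36 and 1.02 per 10 days.

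From the first to the second sampling, with cohort as a covariate, neutrophil, interferon, erythroid and platelet transcripts rose and B cell, T cell and skin and muscle transcripts fell. Mthfd2, a mitochondrial enzyme of 1-carbon metabolism, rose by 2.54 ± 0.20, Asns by 2.78 ± 0.23, Gstt1, a glutathione transferase, by 2.83 ± 0.29 and Steap4 by 2.55 ± 0.23. C5ar1, the receptor of complement C5a, rose by 1.37 ± 0.12, Oas2 by 1.32 ± 0.12 and Ank1, the erythrocyte ankyrin, by 1.33 ± 0.14. Col1a1 fell by 2.95 ± 0.26 and Cd72, a B cell coreceptor, by 0.77 ± 0.08.

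All 20 mature neutrophil genes, all 22 erythroid genes and all 16 platelet genes rose, all of them also adjusted over the list alone. So did 26 of 30 type I interferon-stimulated genes, 26 also adjusted over the list alone. With an estimated correlation the adjusted p = 0.32 for the neutrophil, erythroid and interferon lists and adjusted p = 0.357 for the platelet list. All 17 B cell genes fell, 17 also adjusted over the list alone, and 15 of 18 T cell genes fell with 16 called adjusted over the list alone (adjusted p = 0.32 and adjusted p = 0.404 with an estimated correlation). Of the 13 skin and muscle genes 8 fell and 1 rose, 9 also adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). The list mean fell by 1.06 ± 0.11 (permutation p = 1e-05). The neutrophil list mean rose by 1.60 ± 0.15, with 2.51 ± 0.19 within cohorts 1 to 4 and 0.63 ± 0.20 within cohorts 6 to 9 (permutation p = 0.00236, adjusted 0.0118). Within the same sets the interferon list rose by 0.91 and 0.22, the erythroid list by 1.10 and 0.56, and the skin and muscle list fell by 1.60 and 0.61. The platelet, B cell and T cell lists moved by 0.58, −0.96 and −0.26 within cohorts 1 to 4, and were 0.20, −0.27 and −0.12 within cohorts 6 to 9 (permutation p = 0.0311, 0.0257 and 0.0347, adjusted 0.0578, 0.0514 and 0.0578). In cohort 7 the neutrophil list mean was 6.06 ± 1.26 log2 CPM (SD, n = 10) on day 23 and 5.89 ± 0.89 on day 44, and the B cell list mean was 4.42 ± 0.64 and 4.81 ± 0.60. In all 11326 genes were called, 5648 higher and 5678 lower. The count was 3508 within cohorts 6 to 9, 7269 with the skin and muscle list as a covariate and 1142 with cell composition as covariates.

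Within cohorts of the second sampling, a higher dermatitis score went with more transcripts of mature neutrophil, type I interferon-stimulated and erythroid genes and fewer of B and T cell genes. Per score point Mthfd2 rose by 1.21 ± 0.17 (edgeR adjusted p = 2.4e-07), Asns by 1.10 ± 0.18 and Lipg, endothelial lipase, by 1.47 ± 0.24. Saa3, an acute phase protein, rose by 1.17 ± 0.23 and Isg15, an interferon-induced ubiquitin-like protein, by 0.92 ± 0.17. Kel and Ank1, genes of the erythrocyte membrane, rose by 0.69 ± 0.13 and 0.69 ± 0.12. Fcer2a fell by 0.38 ± 0.06, Ms4a1, the B cell antigen CD20, by 0.29 ± 0.05 and Lef1, a transcription factor of naive T cells, by 0.26 ± 0.05. The slopes of Ighe, Ighg1 and Il4, which encode IgE, IgG1 and interleukin 4, were 0.28 ± 0.23 (adjusted p = 0.34), 0.17 ± 0.09 (adjusted p = 0.1) and −0.07 ± 0.12 (adjusted p = 0.71). Ighg1, at low levels, did differ otherwise. It stood at 2.01 ± 0.92 CPM (SD, n = 50) in conventional and 0.28 ± 0.29 CPM (n = 5) in SPF mice on day 44. In conventional mice it was 0.64 ± 0.68 CPM in the first and 2.32 ± 1.18 CPM in the second sampling (n = 90 each).

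All 20 mature neutrophil genes and all 22 erythroid genes rose with the score, all also adjusted over the list alone (adjusted p = 0.264 and adjusted p = 0.311 with an estimated correlation). The list slopes were 0.57 ± 0.09 and 0.45 ± 0.09 (permutation p = 1e-05 and 2e-05). Among other lists, the platelet and globin means rose by 0.16 ± 0.04 and 0.22 ± 0.08 per score point (permutation p adjusted 0.00114 and 0.024). The skin and muscle list mean fell by 0.22 ± 0.07 (permutation p adjusted 0.01). Of the 30 type I interferon-stimulated genes 17 rose and 1 fell, with 21 called adjusted over the list alone (adjusted p = 0.311 with an estimated correlation). All 17 B cell genes and all 18 T cell genes fell, all also adjusted over the list alone (adjusted p = 0.311 and adjusted p = 0.352 with an estimated correlation). The neutrophil slope was 0.70 ± 0.13 within cohorts 1 to 4 and 0.47 ± 0.14 within cohorts 6 to 9 (permutation p = 0.0045). In the same order the erythroid slope was 0.56 ± 0.12 and 0.31 ± 0.18 (permutation p = 0.0875), the interferon slope 0.30 ± 0.06 and 0.13 ± 0.05 (permutation p = 0.0119, adjusted 0.0596), the B cell slope −0.33 ± 0.09 and −0.20 ± 0.08 (permutation p = 0.0284, adjusted 0.109) and the T cell slope −0.18 ± 0.04 and −0.09 ± 0.05 (permutation p = 0.128). In all 6837 genes were called (3232 up, 3605 down), with 5600 called within cohorts 1 to 4, while within cohorts 6 to 9 edgeR called 0, with 2617 at an unadjusted p under 0.05. The count was 3206 with the rRNA and globin shares and 4 with cell composition as covariates (Mlip, Metap2, Krt15 and Stk3, chosen after their values were seen). With cell composition Metap2 was −0.12 against 0.36 without it, and Stk3 was −0.18 against 0.0016. Mlip (1.62 against 0.85) and Krt15 (−1.66 against −1.41) kept their direction.

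**Figure D4:**
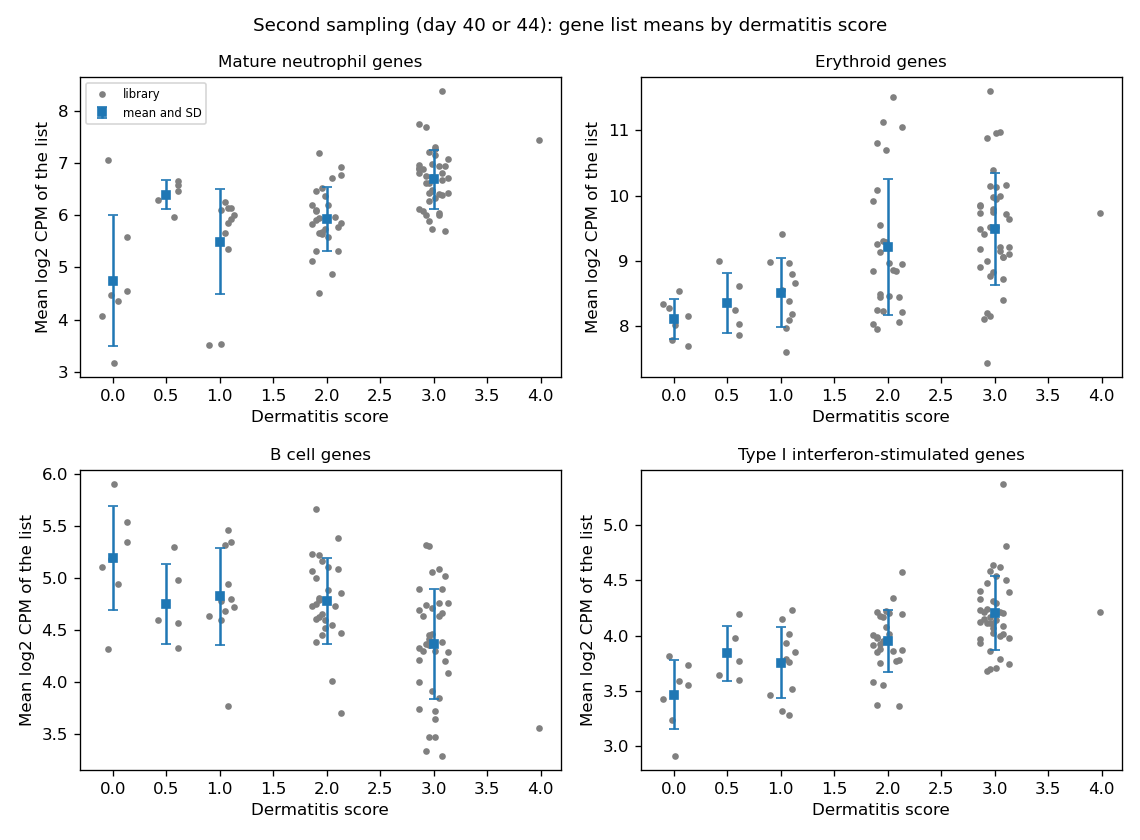
Mean log2 CPM of the mature neutrophil, erythroid, B cell and type I interferon-stimulated lists against the dermatitis score in the 90 second-sampling libraries, with mean and SD where a score has more than 1 library. The erythroid list climbs by 0.45 and the B cell list falls by 0.28 per score point once cohort is accounted for.

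In the first sampling of days 12 to 30, the score went with higher neutrophil and lower B cell genes. Per score point Ly6g rose by 1.09 ± 0.25, Mmp8, neutrophil collagenase, by 1.01 ± 0.19 (edgeR adjusted p = 0.0011), Il1r2, a decoy receptor of interleukin 1, by 0.90 ± 0.17, and S100a8 by 0.89 ± 0.18. Pax5, a regulator of B cell identity, fell by 0.48 ± 0.11, Cd74, the MHC class II invariant chain, by 0.47 ± 0.11 and Fcer2a by 0.49 ± 0.13. Prf1, perforin, fell by 0.28 ± 0.07 and Ccr7, a lymphocyte homing receptor, by 0.27 ± 0.06. The slopes of Ighe, Ighg1 and Il4 were 0.81 ± 0.48 (adjusted p = 0.3), 0.08 ± 0.25 (adjusted p = 0.89) and 0.16 ± 0.18 (adjusted p = 0.63).

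All 20 mature neutrophil genes rose, all 20 also adjusted over the list alone (adjusted p = 0.291 with an estimated correlation). Of the 17 B cell genes 16 fell and 17 were called adjusted over the list alone (adjusted p = 0.291 with an estimated correlation). All 10 MHC class II genes fell, 10 also adjusted over the list alone (adjusted p = 0.291 with an estimated correlation). None of the 22 erythroid genes was called, nor adjusted over the list alone, with a median of 0.14 (adjusted p = 0.645 with an estimated correlation). The difference between the erythroid slopes of the samplings was 0.32 ± 0.18 (permutation p = 0.0212, adjusted 0.317). In all 1808 genes were called (1076 up, 732 down), with 450 for a score above 0 against a score of 0 and 983 without the low-globin libraries of cohorts 6 to 9. With cell composition as covariates edgeR called 0 (886 at an unadjusted p under 0.05), and Ly6g and Fcer2a turned to −0.0152 and 0.0108. Fcer2a is itself a member of the B cell list, whose mean is 1 of these covariates. For the difference of the slopes edgeR called 0 genes, with 2327 at an unadjusted p under 0.05, and DESeq2 called 293.

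The series title names dynamical network biomarkers, which look among other things for a rise of spread between samples and of correlation between genes before onset. Spread was therefore compared between days, which is not a full test of such biomarkers. On day 23, 1542 genes had a higher spread than on the other days (permutation p = 0.0099, the smallest possible), against at most 1092 on that day in 100 permutations. The count of day 16 had a permutation p = 0.0594, and no other day had more than 35 such genes. Over the 500 genes of highest SD, the mean SD was highest on day 12 (0.907, permutation p = 0.0396) and day 16 (0.893, permutation p = 0.0495). Their mean absolute correlation was highest on day 12 at 0.405 (permutation p = 0.149). These p-values were not adjusted over days and measures. Genes of higher spread numbered 1735 over all days with all libraries, 27 within cohorts 1 to 4 and 64 within cohorts 6 to 9. With score 0 alone there were 458 over days 2 to 19, of which 436 were on day 16 (8 libraries). Day 23 is not among these days, so 458 cannot be set against 1735. No permutation p is given for the counts of these subsets.

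**Figure D5:**
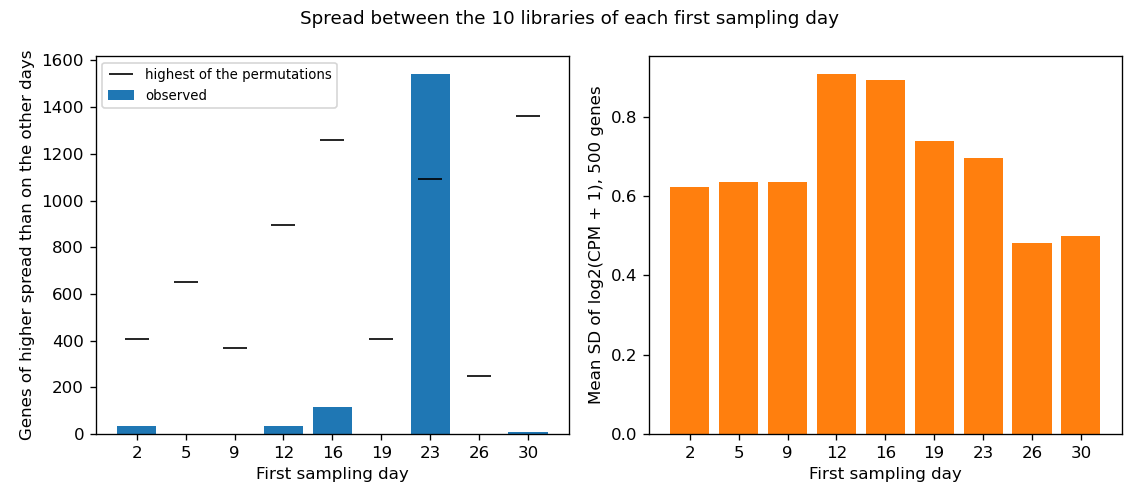
Number of genes with a higher spread on each first sampling day, with the highest number in 100 permutations, and the mean SD (log2 CPM) of the 500 genes of highest SD. Day 23 has 1542 genes, above its highest permuted value of 1092.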

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

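Of the tests in this part, those of the neutrophil dilution of skin and muscle genes and of age in the neutrophil rise were chosen after the results were seen. Several of the 15 measures compared between libraries, among them Steap4, Mthfd2 and Lars2, were also taken from gene results already seen. Over 300 group tests, 36 libraries lay far from the others of their group, where chance alone gives about 1 in 20 groups.

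Among the far libraries, total counts, rounded, were 68000000 in cohort 6 day 40 replicate 6 and 72000000 in cohort 8 day 26 replicate 7. The globin share was 45.3% in SPF day 16 replicate 3, 8.20% in cohort 4 day 40 replicate 2, and 12.2% in cohort 5 day 44 replicate 3. It was 2.63% in cohort 6 day 19 replicate 5, 13.4% in cohort 8 day 40 replicate 6 and 0.728% in cohort 9 day 30 replicate 8, whose mitochondrial rRNA share was 3.54%. The mature neutrophil list mean (log2 CPM) was 6.86 in cohort 8 day 26 replicate 1 and 7.09 in cohort 9 day 30 replicate 2. The B cell list mean was 3.28 in cohort 2 day 40 replicate 8, 3.34 in cohort 5 day 44 replicate 3, 3.73 in cohort 8 day 26 replicate 1 and 3.86 in cohort 9 day 30 replicate 2. The erythroid list mean was 9.40 in cohort 7 day 23 replicate 6 and 9.91 in cohort 8 day 40 replicate 1. The type I interferon-stimulated list mean was 2.65 in cohort 2 day 5 replicate 7 and 4.82 in cohort 9 day 30 replicate 2, and the skin and muscle list mean was 1.01 in cohort 3 day 9 replicate 7 and −0.0737 in cohort 7 day 44 replicate 8.

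Of single genes (log2 CPM), Steap4 was far from its group at 3.72 in SPF day 44 replicate 2, 2.31 in cohort 2 day 40 replicate 6 and 4.42 in cohort 3 day 44 replicate 3. It was also far at 3.92 in cohort 5 day 44 replicate 5, 1.41 in cohort 7 day 23 replicate 2 and 2.87 in cohort 7 day 44 replicate 2. S100a8 was 8.98 in cohort 1 day 2 replicate 7 and 11.8 in cohort 8 day 26 replicate 1. Ccr3 was 2.52 in cohort 9 day 30 replicate 9, and Cd79b was 4.69 in cohort 2 day 40 replicate 8 and 4.68 in cohort 8 day 26 replicate 1. Mthfd2 was 6.30 in cohort 7 day 23 replicate 6. Lars2 was 9.40 in SPF day 16 replicate 3, 2.52 in cohort 5 day 16 replicate 8 and 0.507 in cohort 8 day 40 replicate 10.

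Assignments of the libraries were counted for each comparison, the real one included in every count, so that 1 means that no other split reached it. Of 100 splits, 2 called as many genes as the real one for housing on day 16 (97 genes, highest other 1.6e+02, rounded to 2 digits), 1 on day 44 (3648, highest other 1732), and 1 for the change in cohort 5 (2287, highest other 829). Of 100 splits, 1 did so for any difference among days (10526, highest other 834), 1 for the trend (9569, highest other 367) and 1 for the first-sampling score (1808, highest other 395). Of 46 splits 1 did so for the second against the first sampling (11326, highest other 1898), and of 71 splits 1 for the second-sampling score (6837, highest other 2164). For these comparisons a share under 0.05 of the splits called as many genes. The splits moved single libraries and kept the dispersions of the real fit. Housing and first sampling day are set per cohort, so for them a chance difference between cohorts is not excluded. For the comparisons with 0 genes called by edgeR every split called as many. These were 100 of 100 for the change in SPF mice (highest other 429, 1052 at an unadjusted p under 0.05, DESeq2 0) and 100 of 100 for the difference of the changes (highest other 1.7e+02, 1892 at an unadjusted p under 0.05, DESeq2 55), and 31 of 31 for the difference of the score slopes (highest other 63, 2327 at an unadjusted p under 0.05, DESeq2 293). With a real count of 0 this outcome was fixed in advance and decides nothing. Why some splits called many more genes than the real one was not tested.

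The rise of mature neutrophil genes over the first sampling days could come from the libraries of cohorts 5 to 9, which differ in globin and rRNA share. The second samplings of the same cohorts argue against this: their slope over the cohort's first day was 0.0122 per 10 days (95% interval −0.201 to 0.226), 0.012 times the first-sampling slope of 1.02. Library size predicted 0.0234 of the slope (95% interval −0.0325 to 0.0792). Age alone, alike in both housings, is argued against by the SPF mice. From day 16 to day 44 their list mean changed by 0.22 ± 0.37 (exact permutation p = 0.571), which per 10 days is 0.0766 of the slope (95% interval −0.225 to 0.378). Leaving out 1 SPF library gave 0.0122 (without day 16 replicate 1) to 0.175 (without day 16 replicate 5), with an upper bound of at most 0.448. On day 44 conventional mice were 2.63 ± 0.40 above them. No SPF library is from before day 16, and the difference of the changes in cohort 5 and SPF mice was 1.66 ± 0.60 (permutation p = 0.00816, adjusted 0.118). A rise with time in conventional housing stays open, also where it depends on age.

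The higher spread on day 23 may come from 2 kinds of library within the day or from differences in the score. Without the cohort 6 to 9 libraries under 5% globin, which left 8 on day 23, the count over all days was 977 against 1542. This argues against 2 kinds of library within day 23 as the whole cause, but does not address differences between sets of cohorts. Among the days of cohorts 6 to 9 alone, day 23 had 64 such genes, with all its libraries kept. Why this count is lower was not tested. After the score slope within each day was removed, the day 23 count over all days was 269. With 50 random orders of the scores within days it was 539 to 2005, with a median of 1561.5. The higher spread thus went with mice of different severity on that day. Whether it precedes onset cannot be read from a day when 6 of 10 mice had a score above 0.

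The fall of skin and muscle genes from the first to the second sampling may come from tail tissue carried into the blood or from dilution by neutrophil RNA. Members of the list had a median pairwise correlation of 0.138 within groups, above the upper end of the central range of random lists (0.0713) and under the 0.3 set for carried tissue, so this cannot be told apart at that value. The T cell list fell less than the skin and muscle list by 7.58 standard errors, which argues against dilution alone. In SPF mice the list changed by −0.54 ± 0.29 from day 16 to day 44 (exact permutation p = 0.103), so age of the mice stays open.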

How the results depend on the processing

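The covariates for rRNA and globin share or for the skin and muscle list, the sets of cohorts the choices by globin share and leaving out cohort 5 day 44 replicate 5 were tried after seeing the data; the other alternatives were planned. Scaling by RLE or without globin, rRNA and mitochondrial genes left each count of genes within 1.5 times. Of 213 named gene values 32 kept their direction and side of the threshold under every alternative run for them; of 2859 alternative values 2397 kept both, 415 kept the direction only and 47 turned. Over the whole rule for named genes, 7670 of 9260 alternative values of 707 gene values kept both, 1402 kept the direction only and the rest turned. Where no cause is stated below, the cause was not tested. Genes named beside a count were chosen after their values were seen, and counts in exponent form are rounded to 2 digits.

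For housing on day 16 (97 genes) the count was 55 without a filter on low counts, 460 with DESeq2, 463 with rRNA and globin covariates, 1 with the cohort 5 libraries of day 16 under 5% globin (Gapt). It was 31 to 1.5e+02 leaving out 1 SPF library: 1.5e+02 without day 16 replicate 1, 49 without replicate 2, 31 without replicate 4 and 39 without replicate 5. On day 44 (3648) it was 1996 to 2827 leaving out 1 SPF library (2411, 1996 and 2276 without replicates 2, 3 and 4). It was 303 with composition covariates, of which 75 were shared and 13 of these opposite. With only the 8 conventional libraries of score 0 or 0.5, of 50, it was 0 by edgeR (2861 at an unadjusted p under 0.05). For cohort 5 over time (2287) it was 537 in libraries of 5% globin or more and 2160 to 2357 leaving out 1 SPF library. For the difference of the changes, 0 by edgeR (1892 at an unadjusted p under 0.05), it was 55 with DESeq2 and 1 with rRNA and globin covariates (Gpat3). Any difference among days (10526) gave 15949 without a filter, 5992 with composition covariates, 5082 within cohorts 1 to 4 and 2538 within cohorts 6 to 9. The trend (9569) gave 4263, 4212 and 498 under the last 3. The second against the first sampling (11326) gave 1142 with composition covariates, 3508 within cohorts 6 to 9 and 7269 with the skin and muscle list. The second-sampling score (6837) gave 4 with composition covariates (Mlip, Metap2, Krt15 and Stk3), of which Metap2 and Stk3 changed direction. It gave 4004 for scores of 2 or more against 0 or 0.5 and 3206 with rRNA and globin covariates. Within cohorts 6 to 9 it gave 0 by edgeR (2617 at an unadjusted p under 0.05). The first-sampling score (1808) gave 0 by edgeR with composition covariates (886 at an unadjusted p under 0.05), 450 for scores above 0 against 0 and 983 without low-globin libraries. The difference of the score slopes, 0 by edgeR (2327 at an unadjusted p under 0.05), was 1.8e+02 without a filter and 293 with DESeq2. Genes of higher spread (1735) numbered 458 at score 0 (days 2 to 19 only, with 436 on day 16), 27 within cohorts 1 to 4 and 64 within cohorts 6 to 9. Of the list calls 1 held with an estimated correlation.

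Replicate numbers did not meet the criterion for pairing, a correlation over 0.1 in every pair: 19 of 95 pairs had one, with a mean of 0.0319 for own and −0.00294 for other numbers, and 14 libraries correlated best with their own number. The score did follow the number: it was not lower at the second sampling in 90 of 90 same-numbered pairs (median 85 with permuted numbers, permutation p = 3e-04), so pairing stays open. With the replicate number as a block the count was 46 for day 16, 1 for SPF mice over time (Col10a1), 36 for the difference of the changes, and within 1.5 times for the other comparisons fitted with it.

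Turned with composition covariates were, for the first-sampling score, Ly6g (−0.0152), Fpr2 (−0.0342), Tgm1 (−0.0388) and Fcer2a (0.0108), and for the second-sampling score Fcgr3 (−0.0195), Gstt1 (−0.0365), Apol10a (−0.0589) and Tchh (0.0346). The same covariates turned, for the trend, Lrg1 (−0.0367) and Ly6g (−0.36), for the second against the first sampling Wfdc21 (−0.0430), Ly6g (−0.22), Krt25 (0.95) and Tchh (1.23), and on day 44 Upp1 (−0.23) and Ly6g (−0.49). Trends turned within cohorts 1 to 4 for Car3 (0.0341), Htra1 (0.28), Krt8 (0.35), Hapln1 (0.36), the brachyury gene T (0.36), Chrm2 (0.39), Acan (0.60), Susd5 (0.66) and Peg3 (1.02), and at score 0 for Acan (0.0244). Within cohorts 6 to 9 Dsp turned for the second-sampling score (0.11) and Susd5 (0.85) and Acan (1.42) for the second against the first sampling. With the skin and muscle list that comparison turned for Peg3 (0.15), Htra1 (0.20), Acan (0.55), Susd5 (0.58), Krt25 (1.12) and Tchh (1.76). With rRNA and globin covariates Krt81 (−0.99), Krt83 (−1.785) and Krtap7-1 (−2.08) turned in cohort 5 over time. Without cohort 5 day 44 replicate 5, Krt86 (−0.92), Krt83 (−2.30), Krtap15 (−3.01), Krt81 (−3.33) and Krtap7-1 (−4.24) turned, since that library held nearly all their counts. Their highest values leaving out 1 SPF library were 4.886, 4.655, 8.90, 5.12 and 6.84. SPF libraries are not part of the change in cohort 5, so these values do not test it. No other cohort 5 library was left out alone. Without SPF day 44 replicate 3, Dst (0.15), Car3 (2.77), Peg3 (5.27) and Acan (6.62) turned on day 44. Their lowest values leaving out 1 SPF library were −2.23, −4.77, −4.24 and −5.69. Lars2 on day 16 was −0.02 without SPF day 16 replicate 3.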

Other observations

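The enrichment of process terms was added after the data were seen, as were the test of the eosinophil course and the choice of Ccr3, Alox15 and Siglecf by cohort; the tests of the interferon genes with covariates were set before their results were seen.

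Process terms of the deposited table give gene groups beside the fixed lists, some with the themes of those lists (inflammatory response, translation, B cell activation). The hypergeometric test takes genes as independent, so its p is too small where genes of a term move together. Of the list calls only 1 held with an estimated correlation, and no such correlation was allowed for here. On day 44, genes higher in conventional mice held 71 of 268 genes of the inflammatory response (27.7 expected by chance, adjusted p = 8.92e-11), and genes lower held 58 genes of rRNA processing (17.9 expected, adjusted p = 6.28e-14). Over the first sampling days, genes that fell held 34 of 44 of collagen fibril organization (14.6 expected, adjusted p = 1.16e-06), more genes of translation than the 93.6 expected (adjusted p = 9.93e-28), and 26 of 38 of cytoplasmic translation (12.6 expected, adjusted p = 0.00184). With the second-sampling score, genes that rose held 15 of 19 of heme biosynthesis (adjusted p = 3.32e-05), 34 of 57 of cellular oxidant detoxification and 90 of 229 of ubiquitin-dependent protein catabolism, and genes that fell held 45 of 98 of ribosome biogenesis. With the first-sampling score, genes that fell held 13 of 27 of B cell activation. On day 16 no term passed the adjustment.

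Ccr3 differed between cohorts on the same late day. On day 44 it was 2.97 ± 0.91 CPM (SD, n = 10) in cohort 1, near the 2.30 ± 1.32 CPM of SPF mice (n = 5), and 7.36 ± 2.40, 20.2 ± 7.5, 17.7 ± 8.1 and 11.5 ± 5.1 CPM in cohorts 3, 5, 7 and 9, although the mean score of cohort 1 was 2.05. Alox15 followed the same order, with 0.944 ± 0.389 CPM in cohort 1, 0.798 ± 0.240 CPM in SPF mice and 1.81 ± 0.72, 3.49 ± 1.85, 2.97 ± 1.23 and 2.22 ± 0.71 CPM in cohorts 3, 5, 7 and 9. Siglecf did not, with 2.07 ± 0.96 CPM in cohort 1, 0.706 ± 0.365 CPM in SPF mice and 1.90 to 2.51 CPM in cohorts 3, 5, 7 and 9. The eosinophil list mean (log2 CPM) was 1.55 ± 0.19 in cohort 1, 1.24 ± 0.25 in SPF mice and 1.91 to 2.41 in the other cohorts of that day. These differences were not tested.

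Whether eosinophil transcripts rise before visible dermatitis and then stop rising cannot be told apart from a difference between cohorts. The eosinophil list rose by 1.30 per 10 days over days 2 to 12, when all mice up to day 9 and 8 of 10 on day 12 had a score of 0, and was −0.121 over days 19 to 30, a difference of 1.42 (permutation p = 1e-05, the smallest possible). The list slope on the second-sampling score was −0.11 (permutation p adjusted 0.00175). Days 2 to 12 and 19 to 30 are different cohorts with different globin and rRNA shares. From the first to the second sampling of the same cohorts, the list change was −0.07 ± 0.08 within cohorts 1 to 4 (permutation p = 0.417) and −0.15 ± 0.05 over all cohorts (permutation p adjusted p = 0.00305). Its mean went from 1.37 to 1.55 log2 CPM in cohort 1 and from 1.32 to 1.93 in cohort 2, and from 2.39 to 1.91 in cohort 3 and from 2.45 to 1.88 in cohort 4.

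The rise of interferon-stimulated genes with the second-sampling score may follow the erythroid or the neutrophil share. With the erythroid list as a covariate the slope was 0.148 ± 0.0375 (permutation p = 0.00023), 0.718 of the 0.207 ± 0.035 without it, which argues against the erythroid share as the whole cause. With the mature neutrophil list it was 0.0862 ± 0.0376 (permutation p = 0.0294), 0.417 of the slope, which leaves the neutrophil share open as a cause of part of it.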
